A study of Homo sapiens with 28 samples.

How the data were processed

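The series measured messenger RNA in human effector CD4 T cells (Teff) on 28 arrays of Affymetrix Human Gene 1.0 ST, a 1-colour design that reads each gene with several probes along the transcript. Per the labels' protocols, CD4 T cells were enriched from buffy coats of peripheral blood, Teff were stained with the dye CFSE and incubated with regulatory T cells (Treg) and dendritic cells, and CFSE-positive cells were sorted after 18 h. The sort was therefore meant to leave unstained Treg and dendritic cells behind. RNA was purified on RNeasy columns and labelled with the Ambion WT kit, per the labels' protocols.

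The authors deposited 1 table of linear intensity values, with 1 value per transcript cluster and array. RMA, which corrects background, normalizes across arrays and summarises probes, and Affymetrix Power Tools are named in the submitters' processing notes, and their versions are not given in the sources used here. That the deposited values were linear was read from their range, 0.509 to 8963. Array medians lay between 73.9 and 77.8, so the arrays had been brought to a common scale before deposit and a change in total RNA per cell cannot be seen. Intensities of different genes depend on their probes and were not compared with each other.

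All values were log2-transformed with no pseudocount. Of the 22148 probe sets in the table, 20864 had an entry in the platform annotation used here. That annotation gave 19129 of them 1 gene symbol and 1735 several, and the other 1284 were unnamed here. Only probe sets with 1 symbol were used. The 94 probe sets on sex chromosome genes that could show a donor's sex were left out. For the 625 genes with several probe sets the brightest on average was taken, which left 18254 genes. A gene was tested where the highest of the 14 group means reached the median of all values, 76.5 in intensity or 6.26 in log2. This kept 9930 genes and set aside 8324. No genome was used, so no positions are given.

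Groups and replicate numbers came from the sample titles: 14 groups of 2 arrays, made up of unstimulated Teff, activated Teff and Teff activated together with each of 12 Treg subsets. No 2 arrays held identical values. Nothing in the labels says that the replicates came from separate donors or cultures, so p-values measure only the spread between these samples, which may be technical. The small number of arrays limits the precision.

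Gene-wise comparisons used limma 3.58.1 in R 4.3.3, with 1 coefficient per group, all 28 arrays in 1 fit, 14 residual degrees of freedom and default empirical Bayes moderation (prior degrees of freedom 4.07). Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison at a threshold of 0.05. The comparisons were activated against unstimulated, the equal-weight mean of the 12 co-cultures against activated, each co-culture against activated, 8 pairs of subsets that differ in a named marker, and a moderated F test among the 12 co-cultures. A gene is called changed where it passed that threshold. Differences are on the log2 scale, with the standard error (SE) of the fit. The median residual standard deviation was 0.12.

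The design, the tests, 23 gene lists and the rule for naming genes were fixed before the data were examined. Lists covered T cell activation, cytokines and chemokines, cell cycle, ribosome biogenesis, glycolysis, cholesterol synthesis, the amino acid and stress response, type I interferon response, interferon gamma response, resting T cells, NF-kB targets, IL-2 and STAT5 targets, cAMP and adenosine response, TGF-beta response, anergy and inhibitory receptors, T helper lineage, regulatory T cell markers, and markers of dendritic cells, monocytes, B cells, NK and CD8 cells, red cells and platelets, and handling stress. The 19 lists with at least 5 tested members were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over all 418 tests of a list in a comparison. Camera with an estimated correlation and limma's fry, which tests a list by itself, were run beside it. After the data had been seen, the lists were also tested with each co-culture in turn as the reference of the other 12 activated groups, adjusted over the 19 lists and 12 groups of each reference.

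Genes named in the text were, for activation and for the mean of the co-cultures, the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between the sides (for the mean of the co-cultures, whose 12 group means all lay on 1 side of activated). For each other comparison the 3 largest rises and falls were taken. Up to 4 members of each list with the smallest p were added, with IL2, IFNG, TNF, IL2RA, CD69, MYC, FOXP3 and MKI67 always, and the 10 genes with the smallest p of the F test. Genes that depend on a donor's genotype or clonotype, such as variable HLA class II genes and receptor segments, were excluded. Where a small count of called list members fell outside that rule, its members are named and said to be chosen after their values were seen.

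The activation response retained in co-culture was computed over all tested genes. Each gene was weighted by the activation difference of the arrays with 1 replicate number, and the response of the co-culture was divided by that of activated Teff in the arrays with the other number. This was done both ways, so that no array weighted its own measurement. List means per array were compared between the 24 co-culture and the 2 activated arrays by an exact two-sided permutation test over 325 splits, whose smallest possible p is 0.0062, and among the 12 co-cultures by a permutation test with 100000 resamples. Neither test took account of the replicate number. The exact test also counted the 2 arrays of a group as separate units. Only 1 group was activated without Treg, so where arrays of a group resemble each other its p-values are too small. Because all 12 co-culture comparisons and the activation comparison share the 2 activated arrays, 100 simulations of unchanged groups gave the covariance that this sharing adds.

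Alternatives were no filter and a filter at the 75th percentile, quantile normalization, arrays centred on their medians, moderation with trend and robust settings, the replicate number as a block, a fit on the groups of each comparison only, every probe set counted, and each array left out in turn. Lists of macrophage, mature dendritic cell and T cell core genes were added after the first results had been seen. The procedure was tested on simulated data with the real genes' means and spreads and 200 of 9930 genes changed. For the mean of the co-cultures it recovered 88.1% of the 1.5-fold changes and 100% of the 2-fold changes, with 8 false calls. For Treg.mem against Treg.naive it recovered 82.1% and 100%, with 10 false calls, for Treg.naive co-culture 83.6% and 94%, with 6, and for activation 86.6% and 95.5%, with 15. The simulated noise was independent between genes and arrays and held no effect of the replicate number. These shares average over randomly chosen genes and do not show that a 2-fold change of a variable gene would be called in the real arrays. A retained response set to 90% was returned as 89.7% to 90.2%. Tables and plots were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.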

Results

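Gene expression was measured in human effector CD4 T cells (Teff) that had been left unstimulated, activated for 18 h, or activated for 18 h in the presence of sorted regulatory T cells (Treg), which restrain the activation of other T cells. The co-cultures differed in the surface phenotype of the Treg, giving 12 subsets: Treg.naive, Treg.mem, Treg.CLA-, Treg.DR+, Treg.ICOS+, Treg.ICOS-, Treg.CD39+CD26+, Treg.CD39+CD26-, Treg.CD39-CD26-, Treg.X3+R6+, Treg.X3-R6+ and Treg.X3-R6-, as the labels name them. Each of the 14 groups had 2 arrays. Replicate arrays correlated between 0.9896 and 0.9943 over the tested genes in activated and co-cultured Teff, and at 0.9597 in unstimulated Teff. The series was designed to ask how different Treg subsets alter Teff gene expression.

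Most of the genes tested differed between activated and unstimulated Teff. The labels give 18 h for activated Teff and no time for unstimulated Teff. Stimulation can therefore not be told apart from time in culture, and myeloid markers, given below, rose as well. Among the largest rises were the chemokines CXCL10 (161-fold, log2 difference 7.33, SE 0.2, limma adjusted p = 1.7e-14), CXCL9 (55.6-fold) and CXCL11 (35.9-fold), which are induced by interferons, and the effector cytokines IFNG (65.2-fold, log2 difference 6.03, SE 0.78, adjusted p = 1.6e-06), IL10 (54.1-fold) and IL22 (50.6-fold). TNFRSF9, a costimulatory receptor of activated T cells, rose 39.1-fold, the cytotoxic protease GZMB 31.4-fold, TNIP3, which binds an inhibitor of NF-kB signalling, 46.8-fold, and CCL18, a chemokine made mainly by myeloid cells, 97.4-fold. The largest falls were in TCP11L2 (32.6-fold), SPON1, an extracellular matrix protein (29.2-fold, log2 difference -4.87, SE 0.29, adjusted p = 1e-10), VSIG1 (26.5-fold), the complement receptor CR1 (22.8-fold), KLF3-AS1 (18.7-fold) and the receptor tyrosine kinase EPHA4 (18.4-fold). All 10 rises started from unstimulated levels below the filter of 6.26, and the falls named here apart from EPHA4 ended below it in activated Teff, so these folds and their order rest on values near background. Of 9930 genes tested, 3916 rose and 3193 fell, and 1297 of the rises and 795 of the falls were at least 2-fold (n = 2 arrays per group).

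T cell activation genes rose together, with 19 of 22 tested members higher and none lower (camera adjusted p = 1.5e-05; adjusted p = 0.69 with an estimated correlation). IL2RA, the high-affinity chain of the IL-2 receptor, reached a log2 intensity of 12.09 ± 0.05 against 8.15 ± 0.22 (SD, n = 2), a 15.4-fold rise. CD38 rose 14.7-fold and the transcription factor BATF3 7.41-fold, CD69 rose 2.37-fold (log2 difference 0.4 without unstimulated replicate 2 and 2.09 without replicate 1), and MYC, at 1.37-fold, did not pass the test (adjusted p = 0.11). Cytokine and chemokine genes rose in 16 of 17 members with a median log2 difference of 2.7 (adjusted p = 0.00012; adjusted p = 0.73 with an estimated correlation). IL21, a helper cytokine, rose 29.9-fold, LIF 28.9-fold and TNF 4.76-fold, while IL2 stayed below the filter on low values at 5.57 ± 0.77 against 3.74 ± 0.26. IL-2 and STAT5 targets rose in 14 of 18 members (adjusted p = 1e-05; adjusted p = 0.67 with an estimated correlation), among them CISH, a feedback inhibitor of cytokine signalling, at 11.5-fold and IL2RB at 3.8-fold.

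Genes of growth and division followed. All 22 ribosome biogenesis genes rose (adjusted p = 6.4e-07; adjusted p = 0.69 with an estimated correlation), with BYSL 7.8-fold and NOP16 6.43-fold higher. Cell cycle genes rose in 24 of 25 members (adjusted p = 8.3e-08; adjusted p = 0.69 with an estimated correlation). The DNA replication factors GINS2, GINS1 and MCM4 rose 20.5-fold, 12.7-fold and 10.4-fold, and MKI67 lay below the filter at 4.74 against 3.91. Amino acid and stress response genes rose in 14 of 16 members, led by the mitochondrial folate enzyme MTHFD2 (7.75-fold, SE 0.11 on the log2 scale), and only DDIT3 fell (adjusted p = 0.00028; adjusted p = 0.2 with an estimated correlation). Cholesterol synthesis genes rose in 15 of 18 members (adjusted p = 0.0011; adjusted p = 0.69 with an estimated correlation) and glycolysis genes in 11 of 16 (adjusted p = 0.0057; adjusted p = 0.95 with an estimated correlation), with DHCR7 2.8-fold, HMGCS1 2.38-fold, PKM 3.06-fold and LDHA 3.03-fold higher.

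Interferon gamma response genes rose in 17 of 17 members with a median log2 difference of 2.4 (adjusted p = 8.3e-08; adjusted p = 0.16 with an estimated correlation). These included IDO1, which degrades tryptophan, at 26.3-fold, WARS1 at 14.1-fold and SOCS3 at 8.27-fold. Type I interferon response genes rose in 18 of 25 members, such as IFI44L (5.2-fold) and IFI6 (4.41-fold), while HERC5, IFIT2, ISG20 and MX2 fell (adjusted p = 0.013; adjusted p = 0.85 with an estimated correlation). Resting T cell genes fell in 17 of 20 members (adjusted p = 6.4e-06; adjusted p = 0.36 with an estimated correlation). The glucocorticoid-induced TSC22D3 fell 12.2-fold, the stress-induced SESN1 5.93-fold and KLF2, which maintains quiescence, 4.71-fold, and only the chromatin organiser SATB1 rose. TGF-beta response genes fell in 8 of 11 members, among them SMURF2 (2.14-fold), PMEPA1 (2.45-fold), SKI (1.73-fold) and LDLRAD4 (1.64-fold), while BHLHE40 and TGFBI rose (adjusted p = 0.024; adjusted p = 0.77 with an estimated correlation).

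Dendritic cell markers rose with activation in 10 of 13 members, led by IFI30, a lysosomal thiol reductase of antigen-presenting cells, at 20.8-fold and LAMP3 at 8.39-fold (adjusted p = 0.016; adjusted p = 0.69 with an estimated correlation). In the same arrays 11 macrophage markers, of a list added after the data had been seen, were at least 2-fold higher than in unstimulated Teff, with CYBB at 8.13 against 3.57 and C1QB at 7.94 against 5.45, beside the rise of cytokine and interferon gamma response genes. The remaining lists were not called and had members on both sides. NF-kB targets had 8 of 15 members higher, with IER3 at 3.79-fold, and TNFAIP3 lower (adjusted p = 0.32). Among cAMP and adenosine response genes 6 of 12 rose, including RGS1 at 6.04-fold, and CD55, DUSP1, PDE4D, PER1 and RGS2 fell (adjusted p = 0.99). Anergy and inhibitory receptor genes had HAVCR2 (7.83-fold), LAG3 (2.76-fold) and IKZF1 higher and 6 of 14 lower (adjusted p = 0.63). T helper lineage genes had 7 of 17 higher, such as TBX21 at 4.03-fold, and 6 lower, such as KLRB1 at 5.62-fold (adjusted p = 0.88). Regulatory T cell markers had CTLA4 (4.68-fold), FOXP3 (5.78-fold) and IKZF4 (3.9-fold) higher of 10, and CCR8 lower (adjusted p = 0.59). Handling stress genes had HSPH1 and HSP90AA1 higher and JUN, ZFP36 and DNAJB1 lower of 8 (adjusted p = 0.99). Of lists too small to test, 0 of 2 monocyte markers passed, CD79B was the only B cell marker tested and rose 1.35-fold, NKG7 rose among 2 NK and CD8 markers, and no red cell or platelet marker was tested.

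Counts adjusted over the list alone were the same for every list in activation except IL-2 and STAT5 targets, with 15 higher, and monocyte markers, with 2 higher. Median, mean and test differed in sign for 3 lists, none of them called. Members named above outside the rule for naming genes (HERC5, IFIT2, ISG20, MX2, DDIT3, SATB1, BHLHE40, TGFBI, TNFAIP3, DUSP1, PDE4D, PER1, RGS2, IKZF1, CCR8, NKG7 and DNAJB1) were chosen after their values were seen. The unstimulated arrays differed from each other in early response genes, with SDs of 1.27 for JUN, 1.39 for FOSL2 and 1.71 for RGS1, and a handling stress list mean of 9.51 in replicate 1 and 8.17 in replicate 2. Without unstimulated replicate 1 the falls of DDIT3 and TNFAIP3 turned to differences of 0.1 and 0.02. Without unstimulated replicates 2 and 1 the log2 differences were 1.38 and 3.81 for RGS1, -2.79 and -0.99 for JUN, -3.05 and -0.79 for PER1, -1.74 and -0.43 for DUSP1, -1.84 and -0.62 for IFIT2 and 0.58 and 1.76 for BHLHE40. They were 1.54 and 3.51 for FOSL2, -1.74 and -0.84 for PMEPA1, -1.64 and -0.72 for ZFP36, 0.66 and 0.2 for CD79B, -1.09 and -0.38 for HERC5, -0.14 and -0.35 for ISG20, -1.0 and -0.32 for DNAJB1, 0.4 and 0.05 for IKZF1 and -1.02 and -0.23 for PDE4D, and CCR8 differed by -1.08 and -0.32 without activated replicates 1 and 2. Of the other genes given with a fold, CD38, BATF3, IL21, LIF, GINS1, GINS2, MCM4, NOP16, SOCS3, IDO1, HAVCR2, FOXP3 and IFI30 started from unstimulated levels below the filter, and PMEPA1 ended below it.

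Against this background, adding Treg changed few genes in a fit with no term for the replicate number. Averaged over the 12 co-cultures and compared with activated Teff, IL21 fell by 0.77 on the log2 scale (SE 0.16, 1.71-fold, limma adjusted p = 0.028), and the transcription factor BATF3 fell 1.52-fold (adjusted p = 0.022). Rises included LDLRAD4 (log2 difference 0.45, SE 0.068, 1.37-fold, adjusted p = 0.0077) and PMEPA1 (1.6-fold, adjusted p = 0.024), both feedback inhibitors of TGF-beta signalling. The early response factor EGR1 (1.56-fold), BACH2, a repressor of effector differentiation (1.37-fold), the lectin-like receptor KLRB1 (1.4-fold), the ectonucleotidase ENTPD1, which is CD39 (1.56-fold), and the inhibitory receptor CD5 (1.21-fold) also rose. The largest rises were in genes known from macrophages: SPP1 (3.26-fold, log2 difference 1.7, SE 0.39, adjusted p = 0.046), MMP12 (2.75-fold), MRC1 (2.44-fold), MMP9 (2.39-fold), GPNMB (2.38-fold), PLA2G7 (2.25-fold), FPR3 (2.21-fold) and TGFBI (2.16-fold), together with the cystine transporter SLC7A11 (2.29-fold). In activated Teff, MMP12, MRC1, FPR3, SLC7A11, PMEPA1 and ENTPD1 lay below the filter, so their folds rest on values near background. The log2 difference of MMP9 was 0.72 without activated replicate 2 and 1.79 without activated replicate 1.

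In all, 86 of 9930 genes passed, 77 higher and 9 lower, and 15 of them by at least 2-fold. With the replicate number as a block, 304 passed, these 86 among them. Besides IL21 and BATF3 the lower genes were CLC (2.11-fold) and LGALS17A (1.7-fold), both of the galectin family, so that their probes may not tell family members apart, and LMO7, G0S2, MCTP2, NKX2-4 and SATB1, at 1.45-fold to 1.27-fold. The largest rises and falls were chosen among genes whose 12 group means lay on the same side of activated Teff, and all 12 comparisons share the 2 activated arrays, so their common direction is no further evidence. Leaving out activated replicate 1 or activated replicate 2 left 4 and 0 genes past the threshold, and G0S2 differed by -0.3 and -0.64.

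Several hallmark genes of activation did not pass in this fit, which has no term for the replicate number and does not show them to be unchanged. IFNG averaged 9.79 ± 0.41 over the 12 group means (SD) against 11.04 ± 0.7 in the 2 activated arrays, a difference of -1.25 with an SE of 0.57 (adjusted p = 0.46), and IL22 differed by -1.2 (SE 0.37, adjusted p = 0.17). HAVCR2 (-0.47, adjusted p = 0.052), NFATC1 (0.41, adjusted p = 0.055), ID3 (0.49, adjusted p = 0.058) and TIGIT (0.38, adjusted p = 0.059) lay just outside the threshold. In a limma fit with the replicate number as a block, IFNG (adjusted p = 0.0023), IL22 (0.0017), HAVCR2, NFATC1, ID3 and TIGIT passed. TNF (-0.06), MYC (-0.13), CD69 (0.11), IL2RA (-0.18) and FOXP3 (-0.2) differed by less than 1.2-fold, and IL2 (-0.05) and MKI67 (-0.33) lay below the filter. Without activated replicate 1 and activated replicate 2 the difference of IFNG was -0.75 and -1.74, of TNF 0.15 and -0.28, of MYC 0.04 and -0.3, of FOXP3 -0.06 and -0.34 and of CD69 0.04 and 0.19.

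**Figure D1:**
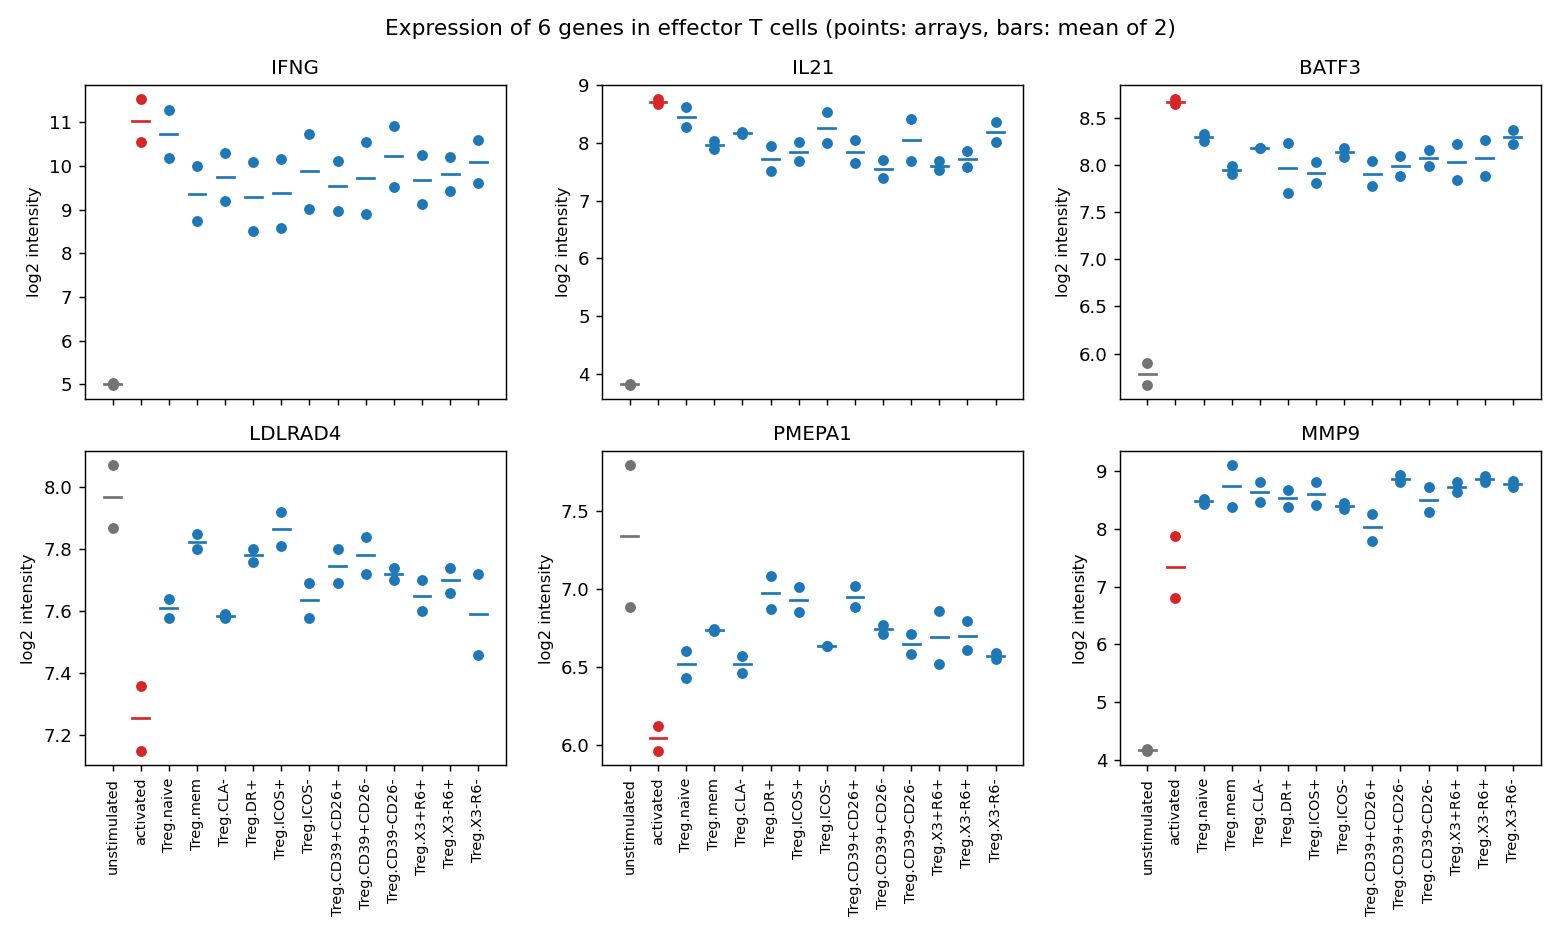
Log2 intensity of 6 genes on each array (points) with the mean of the 2 arrays (bars) in unstimulated, activated and 12 co-cultured groups of Teff. The co-culture means of IL21 and BATF3 lay below activated Teff and those of LDLRAD4, PMEPA1 and MMP9 above it in all 12 groups, while the 2 activated arrays of IFNG spanned 10.54 to 11.53.

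Among the gene lists, cytokine and chemokine genes were lower as a group in co-culture, with a median log2 difference of -0.38 and 13 of 17 members below 0 (camera adjusted p = 0.0013; adjusted p = 0.83 with an estimated correlation). IL21 was the only member called, and 2 were called when adjusted over the list alone. Cell cycle genes had a median of -0.23 with 25 of 25 members below 0 and none called (adjusted p = 8.3e-08; adjusted p = 0.69 with an estimated correlation). UHRF1, which maintains DNA methylation through replication, differed by -0.52 (adjusted p = 0.35), CDC6 by -0.45 and CCNE2 by -0.42, or by -0.19 and -0.66 without activated replicates 1 and 2. Ribosome biogenesis genes (median -0.14, 22 of 22 below 0; adjusted p = 4.7e-05; adjusted p = 0.8 with an estimated correlation) and IL-2 and STAT5 targets (median -0.2, 17 of 18 below 0; adjusted p = 0.00016; adjusted p = 0.69 with an estimated correlation) were lower with no member called, RRS1 differing by -0.36 and GZMB by -0.27. Per array, the exact permutation tests of the list means gave p = 0.18 for cytokines, 0.12 for cell cycle, 0.16 for ribosome biogenesis and 0.08 for IL-2 and STAT5 targets. These tests ignored the replicate number, and the activated cytokine mean itself was 9.02 in replicate 1 and 8.51 in replicate 2. Within replicate numbers 1 and 2 the list medians were -0.38 and -0.41 for cytokines and -0.19 and -0.21 for cell cycle. They were -0.13 and -0.17 for ribosome biogenesis and -0.25 and -0.19 for IL-2 and STAT5 targets, and were not tested.

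TGF-beta response genes were higher, with a median log2 difference of 0.23 and 10 of 11 members above 0 (adjusted p = 3.5e-07; adjusted p = 0.37 with an estimated correlation; fry adjusted p = 0.028). LDLRAD4, PMEPA1 and TGFBI were called, and 5 members when adjusted over the list alone. The list mean was 7.88 in co-culture and 7.52 in activated Teff, and 24 of 24 co-culture arrays lay above both activated arrays (exact permutation p = 0.0062, the smallest this test allows, and 0.058 after adjustment over 19 lists). That test counted arrays rather than groups as units, so its p overstates the evidence from 1 activated group. Resting T cell genes had a median of 0.11 with 15 of 20 members above 0, BACH2 called higher and SATB1 lower (adjusted p = 0.012; adjusted p = 0.69 with an estimated correlation), and adjusted over the list alone 6 were higher and 2 lower. Their list mean gave an exact permutation p of 0.025, or 0.12 after adjustment.

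Anergy and inhibitory receptor genes had CD5 called and a median of 0.088 (adjusted p = 0.19), with 4 higher and 1 lower when adjusted over the list alone. Their list mean lay above both activated arrays in 24 of 24 co-culture arrays (difference 0.08, exact permutation p = 0.0062, adjusted 0.058, again with arrays rather than groups as units). T cell activation genes had EGR1 higher and BATF3 lower, with a median of -0.12 (adjusted p = 0.25). T helper lineage genes, with KLRB1 called (adjusted p = 0.95), regulatory T cell markers, with ENTPD1 called (adjusted p = 0.97), and amino acid and stress response genes, with SLC7A11 called (adjusted p = 0.62), showed no group shift. Adjusted over the list alone, T helper genes had 3 higher and 2 lower and regulatory T cell markers 2 higher. No member was called among glycolysis (adjusted p = 0.99), cholesterol synthesis (0.97), type I interferon (0.99), interferon gamma (0.27), NF-kB (0.76), cAMP and adenosine (0.85) and handling stress genes (1). Median, mean and test differed in sign for 7 lists that were not called and for 0 of the 7 called lists.

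Dendritic cell markers were higher in co-culture by a median of 0.6, with 11 of 13 members above 0 (adjusted p = 5.8e-07; adjusted p = 0.28 with an estimated correlation; fry adjusted p = 0.019). FCER1G (2.06-fold) and TYROBP (1.6-fold), signalling adaptors of myeloid receptors, the chemokine CCL22 (1.66-fold) and the integrin ITGAX (1.52-fold, from a level below the filter) were called, and 7 members when adjusted over the list alone. FCER1G differed by 1.39 and 0.69 without activated replicates 1 and 2. The monocyte markers CD14 (0.84, SE 0.24, adjusted p = 0.13) and CD163 (1.05, SE 0.42, adjusted p = 0.36) did not pass over all genes and passed over the list alone. A B cell marker, CD79B, differed by 0.16 (0.25 and 0.07 without activated replicates 1 and 2), and 2 NK and CD8 markers by a median of -0.1. In the mean of the co-cultures these myeloid markers moved beside the TGF-beta, resting T cell, cytokine, cell cycle, ribosome biogenesis and IL-2 and STAT5 lists, but not in every co-culture. With Treg.naive the mean of dendritic cell markers was 7.91 against 7.43 in activated Teff, and that of cytokines 8.8 against 8.76. With Treg.CD39+CD26+ these means were 7.48 and 8.28. With the mean of a macrophage list on each array as a covariate, added after the data had been seen, 10 genes passed in place of 86. Dendritic cell markers (adjusted p = 0.55), cytokines (0.76) and ribosome biogenesis genes (0.53) were then no longer called, the latter 2 with the opposite direction, nor were IL-2 and STAT5 targets (0.81), while the other 3 list calls stood. With the replicate number also in the model, cytokines (adjusted p = 6.4e-07), ribosome biogenesis genes (0.0015) and IL-2 and STAT5 targets (6.3e-06) were again called lower, and dendritic cell markers were not called (0.54). The covariate's slope came only from differences between the 2 arrays of each group. Macrophage list means were 5.9 and 5.93 in activated Teff and 5.95 or more in co-culture, so both fits extrapolate and cannot decide what the macrophage level accounts for.

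Co-culture with single subsets gave between 0 and 76 called genes in this fit, and between 0 and 499 with the replicate number as a block. Treg.DR+ gave 65 rises and 11 falls. EGR1 rose 1.93-fold, KLRB1 1.74-fold, PMEPA1 1.91-fold, LDLRAD4 1.44-fold (SE 0.093 on the log2 scale, limma adjusted p = 0.02), BACH2 1.51-fold and SPON1, which activation had lowered, 2.5-fold. The inhibitory receptor gene HAVCR2 fell 1.71-fold (adjusted p = 0.028), IL21 1.98-fold (adjusted p = 0.046) and G0S2 1.67-fold, while CD5, NFATC1 and TIGIT rose 1.27-fold, 1.53-fold and 1.46-fold. Cell cycle genes differed most in this co-culture, by a median of -0.49 with 25 of 25 members below 0 and none called over all genes, but 18 when adjusted over the list alone (camera adjusted p = 4.7e-15; adjusted p = 0.44 with an estimated correlation). Cytokine genes differed by a median of -0.62 (adjusted p = 3.6e-05; adjusted p = 0.69 with an estimated correlation).

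Treg.ICOS+ gave 49 rises and 5 falls. LDLRAD4 (1.52-fold, adjusted p = 0.014), PMEPA1 (1.85-fold), ID3, an inhibitor of helix-loop-helix factors (1.75-fold), EGR1 (1.69-fold), KLRB1 (1.68-fold), CD5 (1.31-fold) and NFATC1 (1.54-fold) rose, as did FPR3, MMP9 and PLA2G7 (2.33-fold to 2.45-fold) and CCL22 (2.03-fold). LGALS17A (2.04-fold), BATF3 (1.69-fold) and the cytokine IL26 (1.61-fold) fell. Treg.CD39+CD26+ gave 27 rises and 5 falls, with CLC lower by 3.51-fold (adjusted p = 0.017), LGALS17A by 2.14-fold and the small nucleolar RNA SNORD82 by 1.89-fold. PMEPA1 (1.88-fold), EGR1 (1.85-fold), EEIG1 (1.74-fold), ID3 (1.72-fold), BACH2 (1.55-fold) and CD5 (1.37-fold, adjusted p = 0.016) rose. Its macrophage list mean, 6.18, was the lowest of the 12 co-cultures, against 5.92 in activated Teff and 6.65 in the highest, Treg.X3-R6+.

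Treg.CD39+CD26- gave 8 rises, with SLC7A11 at 3.17-fold, MMP9 at 2.89-fold, PLA2G7 at 2.85-fold and LDLRAD4 at 1.44-fold, and 1 fall, CLC, at 3.55-fold. Treg.X3-R6+ gave 11 rises, among them MMP9 (2.86-fold), KYNU, an enzyme of tryptophan breakdown (2.78-fold), FPR3 (2.76-fold) and TYROBP (2.05-fold). Treg.mem gave 6 rises, with PLA2G7 at 2.64-fold, QPCT at 2.05-fold, the lysosomal protease LGMN at 1.75-fold and LDLRAD4 at 1.48-fold, and Treg.X3-R6- gave 1, MMP12, at 5.0-fold (adjusted p = 0.041). Limma called 0 genes for Treg.naive, Treg.CLA-, Treg.ICOS-, Treg.CD39-CD26- and Treg.X3+R6+, where 389, 393, 471, 339 and 608 genes had an unadjusted p under 0.05. If all 9930 genes were unchanged, a share of 0.05 would fall there, more than each of these except the 608 of Treg.X3+R6+. The counts of called genes depend on leaving out the replicate number. With it as a block, 17 genes passed for Treg.CLA- and 79 for Treg.X3+R6+, and 0 for Treg.naive, Treg.ICOS- and Treg.CD39-CD26-. KYNU, QPCT, SPON1, ID3, PMEPA1, FPR3, SLC7A11 and MMP12 lay below the filter in activated Teff, so their folds rest on values near background, and the differences of MMP9 with Treg.ICOS+, Treg.CD39+CD26- and Treg.X3-R6+ ran from 0.73 to 1.0 without activated replicate 2 and from 1.8 to 2.07 without activated replicate 1. ID3 with Treg.ICOS+ differed by 1.17 and 0.44 without that co-culture's replicates 1 and 2. Adjusted over the 12 comparisons together, a choice made after the data had been seen, 0 genes passed for any subset. Leaving out either activated array or either array of the co-culture moved the counts to between 0 and 3 for Treg.DR+, Treg.CD39+CD26+ and Treg.CD39+CD26-, 0 and 2 for Treg.X3-R6+ and Treg.X3-R6- and 0 and 1 for Treg.mem, and for Treg.ICOS+ to 226 without its replicate 1, 0 without its replicate 2, and 1 and 2 without activated replicates 1 and 2.

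The same lists were called in several subsets, as comparisons that share 2 activated arrays can be without an effect. TGF-beta response genes were called higher in 12 of 12 subsets, with medians from 0.16 in Treg.naive to 0.38 in Treg.ICOS+ (lowest adjusted p = 0.37 with an estimated correlation), and dendritic cell markers in 11 of 12, with medians from 0.1 in Treg.CD39+CD26+ to 0.8 in Treg.CD39+CD26- (lowest adjusted p = 0.16 with an estimated correlation). Ribosome biogenesis genes were called lower in 11 subsets, cytokine and cell cycle genes in 10 and IL-2 and STAT5 targets in 9 (lowest adjusted p = 0.76, 0.69, 0.44 and 0.59 with an estimated correlation). Resting T cell genes were called higher in 7, interferon gamma response genes lower in 3 and T cell activation genes lower in 2 (lowest adjusted p = 0.51, 0.59 and 0.92 with an estimated correlation). In Treg.naive, cytokine and cell cycle genes had medians of 0.08 and 0.012 and were not called. Over all comparisons 127 of 418 list tests passed, none of them with an estimated correlation, and fry called 31, of which 26 were among the 127. To see how many calls a shared reference brings, a test chosen after the data had been seen took each co-culture in turn as the reference of the other 12 groups that were activated, adjusting within each reference. The TGF-beta list was then called higher in at most 6 of 12 groups, against 12 with activated Teff as the reference. Dendritic cell markers were called higher in up to 11 groups, as many as with activated Teff. Resting T cell genes were called higher in up to 8, against 8 with activated Teff under this adjustment. Cytokines were called lower in up to 8, cell cycle genes in up to 9, ribosome biogenesis genes in up to 10 and IL-2 and STAT5 targets in up to 5, against 10, 10, 11 and 9. In the opposite direction, with Treg.DR+ as the reference cell cycle genes were called higher in 12 of 12 groups. With that reference IL-2 and STAT5 targets were also called higher in 10 groups, cytokines in 9 and ribosome biogenesis genes in 7, and resting T cell genes lower in 10. With Treg.mem as the reference IL-2 and STAT5 targets were called higher in 10 groups and T cell activation genes in 8. With Treg.ICOS+ cytokines were called higher in 7 and ribosome biogenesis genes in 6. Over all co-culture references dendritic cell markers were called lower in up to 8 groups and the TGF-beta list in up to 5. Large counts thus also arose with a co-culture as the reference. With 13 possible references this count alone cannot exclude chance.

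Direct comparisons between subsets tested whether a named surface marker separated the co-cultures. Limma called 0 genes in each of the 8 pairs. At an unadjusted p under 0.05 there were 241 genes between Treg.mem and Treg.naive, 111 between Treg.ICOS+ and Treg.ICOS-, 541 between Treg.CD39+CD26+ and Treg.CD39-CD26-, 169 between Treg.CD39+CD26- and Treg.CD39-CD26-, 923 between Treg.CD39+CD26+ and Treg.CD39+CD26-, 106 between Treg.X3+R6+ and Treg.X3-R6-, 76 between Treg.X3-R6+ and Treg.X3-R6-, and 39 between Treg.X3+R6+ and Treg.X3-R6+. The smallest adjusted p of any pair was 0.086, for Treg.CD39+CD26+ against Treg.CD39+CD26-. Among all 12 co-cultures the F test also called 0 genes, with 301 at an unadjusted p under 0.05, so the subsets are not shown to differ in their effects on single genes. If all 9930 genes were unchanged, a share of 0.05 would fall there, more than the 301 and every pair's count except 541 and 923. Without Treg.CD39+CD26+ replicate 2, 22 genes passed against Treg.CD39+CD26- and 3 against Treg.CD39-CD26-. IDO1 had the smallest p of that test (0.00027, adjusted p = 1), its means running from 7.73 with Treg.CD39+CD26+ to 9.35 with Treg.X3-R6+ against 8.53 in activated Teff. Among the 12 co-cultures, per-array means of the TGF-beta list gave a permutation p of 0.003, which was 0.057 after adjustment over 19 lists, running from 7.79 with Treg.naive to 7.97 with Treg.ICOS+.

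The size of the activation response, weighted over all tested genes, was little altered. Over all tested genes, co-cultured Teff retained a mean of 93.7% of it, with 93.5% and 93.9% from the 2 ways of combining the replicates. Treg.DR+ had the lowest value, 87.0% ± 0.52 (SD of 2 values), followed by Treg.ICOS+ at 90.7% ± 1.5 and Treg.CD39+CD26+ at 91.2% ± 3.2, and Treg.naive the highest, 98.9% ± 3.2. Treg.CD39-CD26- retained 98.5% ± 3.1. These shares also count myeloid genes that rose with activation and were higher still in co-culture, so they do not measure Teff alone. Dendritic cell markers retained a mean of 118%. Cytokines retained 86.4%, NF-kB targets 86.6%, cell cycle genes 89.8% and IL-2 and STAT5 targets 90.4%. Interferon gamma response genes retained 99%, cholesterol synthesis genes 100% and amino acid and stress response genes 103%. The shares of the lists were not tested against each other. The mean of the T cell activation list was 8.96 in co-culture and 8.99 in activated Teff (exact permutation p = 0.73), and did not differ detectably among the 12 co-cultures (permutation p = 1). Both permutation tests ignored the replicate number, and the list mean was 9.11 and 8.88 in activated replicates 1 and 2. The activation and co-culture differences had a covariance across genes of -0.055, against -0.01 in simulations where only the shared activated arrays linked them, and a correlation of -0.4 against a simulated -0.68. Genes are not independent replicates, and no test was made within a subset.

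**Figure D2:**
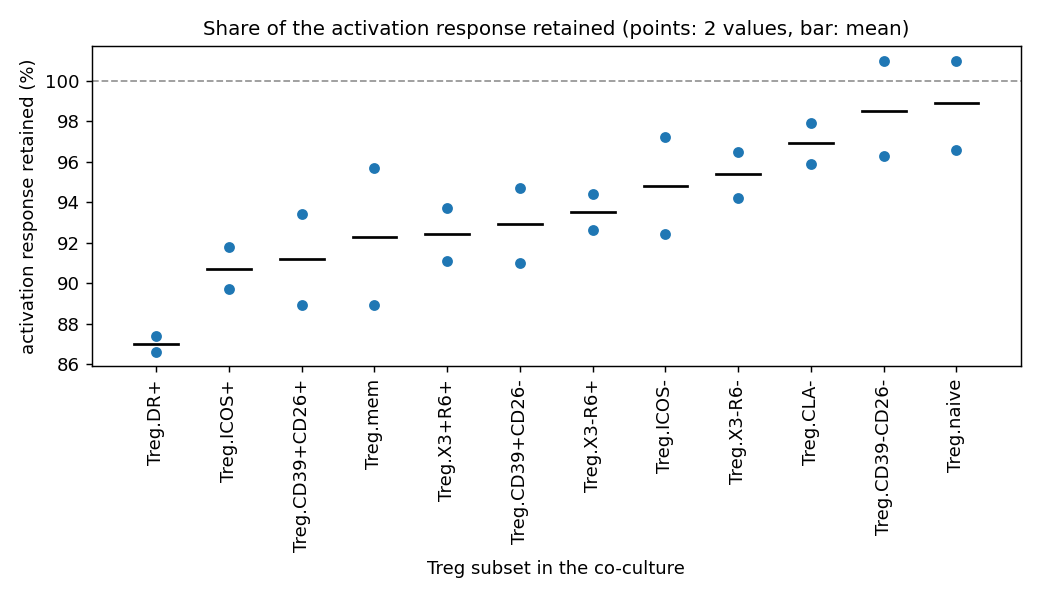
Share of the activation response retained in each co-culture, in percent, with both values (points) and their mean (bar), subsets ordered by mean, and a dashed line at 100%. The means ran from 87.0% with Treg.DR+ to 98.9% with Treg.naive, and the 2 values of Treg.mem lay at 88.9% and 95.7%.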

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

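Every test in this part was chosen in advance. Differences between 2 co-cultures were tested directly, list by list, for the 8 pairs of subsets that differ in a named marker. Of these 152 tests, 32 gave an adjusted p under 0.05 at camera's preset correlation and none with an estimated correlation, where the lowest adjusted p was 0.16. Values are the median log2 difference of the list, first subset minus second. List means by replicate are given for some of these differences only. Groups of 2 arrays allowed no test for a single deviating array.

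Treg.mem differed from Treg.naive in 8 lists: cytokines by -0.49, cell cycle by -0.23, ribosome biogenesis by -0.21, IL-2 and STAT5 targets by -0.19, T cell activation by -0.17, interferon gamma response by -0.13, type I interferon response by -0.11 and TGF-beta response by 0.15 (lowest adjusted p = 0.59 with an estimated correlation). The cell cycle list means were 8.75 against 8.79 in replicate 1 and 8.15 against 8.56 in replicate 2, so that difference came mainly from replicate 2. Treg.ICOS+ differed from Treg.ICOS- in cytokines by -0.21, cell cycle by -0.15, ribosome biogenesis by -0.085, TGF-beta response by 0.11 and anergy and inhibitory receptors by 0.092 (lowest adjusted p = 0.44 with an estimated correlation). The anergy list means were 9.0 against 8.99 in replicate 1 and 9.05 against 8.93 in replicate 2, so that difference came mainly from replicate 2.

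Treg.CD39+CD26+ differed from Treg.CD39-CD26- in dendritic cell markers by -0.37, cytokines by -0.32, cell cycle by -0.16, interferon gamma response by -0.04 and resting T cell genes by 0.14 (lowest adjusted p = 0.36 with an estimated correlation). Treg.CD39+CD26- differed from Treg.CD39-CD26- in cytokines by -0.28, cell cycle by -0.24, ribosome biogenesis by -0.14, dendritic cell markers by 0.14 and type I interferon response by 0.073 (lowest adjusted p = 0.67 with an estimated correlation). Their cell cycle list means were 8.31 against 8.74 in replicate 1 and 8.41 against 8.46 in replicate 2, so that difference came mainly from replicate 1. Treg.CD39+CD26+ differed from Treg.CD39+CD26- in dendritic cell markers by -0.57 (adjusted p = 1.2e-09; adjusted p = 0.16 with an estimated correlation; fry adjusted p = 0.025) and in interferon gamma response by -0.029. Adjusted over the list alone, 7 dendritic cell markers were lower.

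Treg.X3+R6+ differed from Treg.X3-R6- in cell cycle by -0.16, type I interferon response by 0.068, interferon gamma response by 0.061 and TGF-beta response by 0.056 (lowest adjusted p = 0.67 with an estimated correlation). The interferon gamma list means were 9.93 against 9.93 in replicate 1 and 9.99 against 9.86 in replicate 2, so that difference came from replicate 2. Treg.X3-R6+ differed from Treg.X3-R6- in cell cycle by -0.11 and ribosome biogenesis by -0.07 (lowest adjusted p = 0.95 with an estimated correlation). Treg.X3+R6+ differed from Treg.X3-R6+ in type I interferon response by 0.023 (adjusted p = 0.92 with an estimated correlation). Its list means were 8.4 against 8.33 in replicate 1 and 8.15 against 8.18 in replicate 2, so the direction was not the same in both.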

How the results depend on the processing

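The adjustment over the 12 comparisons together and the fits with a macrophage covariate were chosen after seeing the data, and the other alternatives in advance. Apart from leaving out arrays, 148 counts stayed within 1.5 times the reported one and 55 did not, and of the values of named genes 1528 stayed on their side of the threshold in the same direction, 155 lost a call, 37 gained one and none reversed. All 127 list shifts kept their direction under quantile normalization, centring and the replicate block, with 118, 118 and 127 still past the threshold. The macrophage covariate, run for the mean of the co-cultures only, left 6 lists past the threshold in place of 7: cytokines, ribosome biogenesis, IL-2 and STAT5 targets and dendritic cell markers lost their calls, the first 2 turning to higher, and glycolysis (lower, adjusted p = 3.6e-14), cholesterol synthesis (lower, 9.1e-05) and type I interferon response (higher, 0.0044) gained one. With the replicate number as well, 8 passed, cytokines, ribosome biogenesis and IL-2 and STAT5 targets being lower again, dendritic cell markers not called, and glycolysis (4e-07) and interferon gamma response (0.014) lower. No scaling moved the median of all genes by more than 0.1, but the share of activation genes that rose was 49.8% under quantile normalization against 55.1%. Genes near background limit the filter alternatives, since 8324 of 18254 genes lay below it. Except where more or fewer genes or arrays were used, the cause was not tested.

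With no filter the counts were 0 for Treg.mem, 3 for Treg.DR+, 3 for Treg.ICOS+, 7 for Treg.CD39+CD26+, 1 for Treg.X3-R6+ and 0 for Treg.X3-R6-. A filter at the 75th percentile gave 4149 for activation, 52 for the mean of the co-cultures, 11 for Treg.mem, 0 for Treg.X3-R6- and 1 between Treg.CD39+CD26+ and Treg.CD39+CD26-. Quantile normalization gave 0 for Treg.mem, 33 for Treg.DR+, 35 for Treg.ICOS+, 0 for Treg.X3-R6+ and 0 for Treg.X3-R6-, and centring gave 3 for Treg.mem, 26 for Treg.DR+, 18 for Treg.CD39+CD26+ and 6 for Treg.X3-R6+. Of the genes passing for Treg.CD39+CD26+ 72.2% were higher with centring against 84.4%, and for Treg.CD39+CD26- 75% with either scaling against 88.9%. Trend and robust moderation gave 18 for Treg.mem, 17 for Treg.CD39+CD26- and 0 for Treg.X3-R6-. A fit on the groups of a comparison only gave 199 for the mean, 35 for Treg.mem, 72 for Treg.CLA-, 256 for Treg.DR+, 0 for Treg.CD39+CD26+, 70 for Treg.CD39+CD26-, 18 for Treg.CD39-CD26-, 2 for Treg.X3-R6+ and 0 for Treg.X3-R6-. Counting every probe set gave 25 for Treg.X3-R6+ and 0 for Treg.X3-R6-. Adjusting over the 12 comparisons together gave 0 for Treg.mem, Treg.DR+, Treg.ICOS+, Treg.CD39+CD26+, Treg.CD39+CD26-, Treg.X3-R6+ and Treg.X3-R6-. The macrophage covariate gave 10 for the mean, and 23 together with the block. Against 127 list shifts called by camera, 0 passed with an estimated correlation and fry called 31 of the 418 tests, 26 of them shared with camera. Over the T cell activation list only, the retained response was 94.35% for the mean, 92.8% for Treg.CLA-, 93.56% for Treg.DR+, 95.51% for Treg.CD39+CD26+, 95.76% for Treg.CD39+CD26- and 94.42% for Treg.X3+R6+.

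Replicate numbers were tested for pairing by correlating the difference between the 2 replicates of each group across groups, gene by gene. In 75 of 78 pairs of activated or co-cultured groups the correlation was above 0.1 (median 0.42, lowest -0.023), short of the rule that all be above it, and no correlation with the unstimulated group passed 0.14. All 26 arrays matched an array of their own number best, and the first principal component, with 31.2% of the variance, separated the numbers in 13 of 13 groups. With the replicate number as a block the counts were 7407 for activation, 304 for the mean, with all 86 genes among them, 204 for Treg.mem, 17 for Treg.CLA-, 499 for Treg.DR+, 373 for Treg.ICOS+, 236 for Treg.CD39+CD26+, 127 for Treg.CD39+CD26-, 79 for Treg.X3+R6+, 142 for Treg.X3-R6+, 28 for Treg.X3-R6- and 0 for the other subsets, the pairs and the F test. In the mean of the co-cultures IFNG (-1.25, adjusted p = 0.0023) and IL22 (-1.2, adjusted p = 0.0017) then passed, as did HAVCR2, NFATC1, ID3, TIGIT and 9 other named genes.

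Leaving out 1 array of a group leaves a lone array that is assumed to vary like the other groups, and the retained response needs both replicates. Counts ranged from 6208 to 7029 for activation and from 0 to 127 for the mean of the co-cultures, with 0 and 4 without activated replicates 2 and 1 and 66 to 127 without any other array. They ranged from 0 to 1 for Treg.naive, Treg.mem, Treg.CLA-, Treg.CD39-CD26- and Treg.X3+R6+, the 1 in each without activated replicate 1, from 0 to 3 for Treg.DR+, Treg.CD39+CD26+ and Treg.CD39+CD26-, from 0 to 226 for Treg.ICOS+, from 0 to 2 for Treg.X3-R6+ and Treg.X3-R6-, and were 0 for Treg.ICOS-. They ranged from 0 to 3 between Treg.CD39+CD26+ and Treg.CD39-CD26- and from 0 to 22 between Treg.CD39+CD26+ and Treg.CD39+CD26-, both highest without Treg.CD39+CD26+ replicate 2, and were 0 for the other pairs and the F test. Of the values of named genes 2683 stayed, 327 lost a call, 16 gained one and 4 reversed: TNF (-0.28 to 0.15) and MYC (-0.3 to 0.04) in the mean of the co-cultures without activated replicate 1, and DDIT3 (-1.31 to 0.1) and TNFAIP3 (-1.62 to 0.02) in activation without unstimulated replicate 1.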

Other observations

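The tests of array normalization, of replicate numbers and of myeloid RNA against the TGF-beta list were chosen before their results were seen, and the other tests in this part after.

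The share of the activation response retained in co-culture was also computed within each gene group. The means over the 12 subsets were 80.1% for anergy and inhibitory receptors, 85.0% for TGF-beta response, 86.1% for T helper lineage, 86.4% for cytokines, 86.6% for NF-kB targets, 89.8% for cell cycle, 90.6% for ribosome biogenesis and 91.5% for resting T cell genes. Interferon gamma response genes retained 99%, cholesterol synthesis genes 100%, amino acid and stress response genes 103% and dendritic cell markers 118%. Handling stress genes gave 30.3% and 86.8% in the 2 ways of combining replicates. These shares were not tested against each other.

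Among the 12 co-cultures, none of the 10 genes with the smallest p of limma's F test passed the threshold (each adjusted p = 1), so the ranges given here are not shown to exceed chance. CD40, the receptor that T cell help engages, ran from 5.57 with Treg.CD39+CD26+ to 6.41 with Treg.X3-R6-. The inflammatory cytokine IL1B ran from 5.2 with Treg.CD39+CD26+ to 6.52 with Treg.X3-R6+, SOD2 from 8.73 to 9.44 in the same co-cultures and NRP1 from 5.5 with Treg.CD39+CD26+ to 6.39 with Treg.X3-R6-. ASF1B, a histone chaperone of replicating cells, was lowest with Treg.DR+, at 6.71, and 7.37 with Treg.naive.

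Myeloid genes were higher in co-culture although the sort on CFSE would remove unstained cells. Of 28 macrophage markers on the array, 96.4% had a positive difference, with a median of 0.48 above all 10000 random lists and MRC1 and C1QB called, and the abundant CTSB had a mean of 10.87 against 10.49 in activated Teff, CD68 9.36 against 8.84 and CYBB 9.27 against 8.13. Only 4 of these markers were above the filter in unstimulated Teff and 3 are in a list above, so macrophage-like cells or their RNA in the sorted fraction may account for the rise. The median was still 0.48 after quantile normalization. RMA had already normalized the arrays, so this step could change little and does not decide on array normalization. More of the mixture already present in the activated arrays cannot be told apart from a change in its kind, since the medians of mature dendritic cell and macrophage markers differed by -0.82 (permutation p = 0.015 over genes) on only 4 mature dendritic cell markers, and of all 19 such markers, 9 of them in a list above, the median was 0.036 with none called.

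Cytokine and cell cycle lists were lower in co-culture by camera at its preset correlation (adjusted p = 0.83 and adjusted p = 0.69 with an estimated correlation). The list means had an exact permutation p of 0.18 and 0.12 in tests that ignored the replicate number. T cell core genes, 18 on the array and in no other list, had a median of 0.11, with 15 above 0 and none called. The list did not fall, but this cannot exclude dilution of Teff RNA. Treg are T cells, so their RNA need not lower it. Some members also changed with activation, UBASH3A from 8.54 to 7.65 and CD28 from 10.5 to 11.02, so a change in activation could offset a fall. The cell cycle median was -0.19 and -0.21 within replicate numbers 1 and 2, each against 1 activated array. Each group held 1 array of each number, so a difference between the numbers common to all groups cancels in this comparison. These medians are therefore no separate test of it. With the macrophage level of each array and the replicate number in the model the cytokine median was -0.46 and the list mean differed by -0.46 (SE 0.11). With the macrophage level alone the median was 0.19 and the list mean differed by 0.21 with an SE of 0.31, too wide to decide. The slope came only from differences between the 2 arrays of each group, and all co-culture arrays had a higher macrophage level than both activated arrays. Both fits therefore extrapolate and cannot decide whether the macrophage level is the source. Over the 12 group means cytokine and macrophage levels had r = 0.026 (permutation p = 0.93, also 0.93 adjusted over 3 relations) and rho = 0.035 (permutation p = 0.92), with r = -0.21 without the 2 farthest subsets, and no biological explanation was tested.

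The TGF-beta response list was called higher in 12 of 12 co-cultures by camera at its preset correlation and in none with an estimated correlation (lowest adjusted p = 0.37). Without TGFBI, which macrophages also express, the median stayed at 0.23, and with the macrophage level also in the model it was 0.33. The fit with the macrophage level extrapolates, as for cytokines, and cannot decide on myeloid RNA as the source. Over the 12 group means this list and the macrophage list had r = -0.41 (permutation p = 0.19, 0.57 adjusted over 3 relations) and rho = -0.14 (permutation p = 0.67), with r = -0.14 without the 2 farthest subsets. The median lay at percentile 99.92 of 10000 random lists matched on the activation difference, whose median was 0.082, so the list rose more than most genes with a like activation difference. The random lists were matched member by member and leave out correlation among list members, and the activation difference rests on the same activated arrays. The percentile therefore cannot decide on a general shift back toward the unstimulated state. No biological explanation was tested, and the pattern rests on the same 2 activated arrays throughout.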
